A study of Homo sapiens with 12 samples.

How the data were processed

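RNA from 12 cultures of EA.hy926, an endothelial line made by fusing human umbilical vein endothelial cells with a lung carcinoma line, was hybridised to Illumina BeadChips. Per the labels, the cells lacked estrogen receptor alpha (gene ESR1) and were stably transfected with a vector carrying the human receptor ("receptor cells") or with the empty backbone ("control cells"). They were selected with puromycin, kept in serum-free medium for 24 h, then given ethanol vehicle or 10 nM 17-beta-estradiol for 16 h. Each of the 4 groups had 3 arrays, called biological replicates by the study. The labels do not say whether the replicate numbers stand for separate clones or for cultures of the same cells.

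The deposited non-normalized file held a bead summary intensity per probe and array. The deposited detection p-value of each intensity came in steps of 1 over 770, the number of negative control probes that such steps imply. The authors also deposited a table of normalized intensity, for which the notes name lumi without a version. On a linear scale its 12 arrays shared their quantiles to within a relative difference of 0.00151, and the series value table held the same values, with a largest difference of 0.

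Of 47322 probes, 1 (CDC25C) lacked values on 4 arrays, those of receptor cells replicates 1 and 2 under vehicle and estradiol, and 47321 were used. Intensities were background corrected with the detection p-values, quantile normalised and put on the log2 scale with an offset of 16 (neqc in limma 3.58.1, R 4.3.3). Values are called normalized log2 levels. Figures were drawn with matplotlib 3.10.9 (numpy 2.4.6, Python 3.11.15). Older gene symbols were updated from a human gene list: 27035 probes had a current symbol, 4675 were updated, 12341 kept a symbol that the table lacked, and 3270 had none. Probes were kept when their detection p-value was under 0.05 on at least 3 arrays, which left 21476, of which 19953 were named. Each gene was represented by its probe with the highest mean, giving 15249 genes, 3619 of them with several probes. Other probes called in the opposite direction existed for CPEB2 and PARPBP, in the unliganded comparison, and for 0 genes elsewhere.

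A model with 1 mean per group was fitted to all 12 arrays with limma (8 residual and 4.62 prior degrees of freedom). Moderated two-sided tests were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. The 5 contrasts were receptor over control under vehicle (unliganded receptor), estradiol over vehicle in receptor cells, the same in control cells, the difference between those responses, and receptor over control under estradiol. Standard errors (SE) are those of the fit, with 3 arrays per group, and SDs are between arrays of a group. The level of ESR1 was compared by an exact permutation test. Arrays give no counts, so their number and the background limit the precision. A fold against a group not detected on any of its arrays is written as "at least" the fold over the level where detection starts.

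A total of 23 gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which tests whether the members move on balance in a single direction, were run beside it. The lists were estrogen-responsive genes, endothelial identity, epithelial markers, mesenchymal and smooth muscle markers, leukocyte markers, mitosis, DNA replication, adhesion molecules with chemokines and NF-kB targets, interferon-stimulated genes, antigen presentation, extracellular matrix, angiogenic and Notch signalling, vascular tone and coagulation, cholesterol synthesis, NRF2 targets, the unfolded protein response, ATF4 targets, hypoxia and glycolysis, p53 targets, TGF-beta and BMP targets, immediate early genes, nuclear receptors with cofactors, and reference genes. The groups, contrasts, tests, lists, the rule for naming genes and most alternatives were chosen before the data were examined. The rule named, per comparison, the 6 highest and 6 lowest folds among called genes whose arrays did not overlap between groups, without placeholder symbols, and the 3 called members with the smallest p of each list with a called shift or at least 2 called members. It also named 11 list members fixed in advance, called or not, and genes called in opposite directions for the unliganded receptor and for estradiol in receptor cells. The genes bounding neighbouring-gene blocks, the genes found with the within-line block and the genes lost on position correction were named after their values were seen. Some genes that the rule names are not reported here.

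Whether replicate numbers pair the arrays was checked on deviations from group means, across genes. Vehicle and estradiol arrays of the same number correlated at 0.76, 0.39 and 0.67 in receptor cells and at 0.08, 0.03 and 0.11 in control cells. The planned model held no pairing. A fit with the replicate number as a block gave counts of 1736, 11, 0, 5 and 1565 genes for the 5 contrasts, and blocks set within each cell line were added after the values were seen.

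Alternatives changed the normalisation, the source of values, the detection filter, the probe choice, the arrays in the fit, the replicate block, the variance model, array weights, a fold minimum of 1.5, the set test and each array in turn. A slide could not serve as a block because the files name no slides. The search for shifts of neighbouring genes was chosen after the data were seen. Genes with a mean normalized log2 level of at least 6 were put in chromosome order and divided into blocks of 51, and block medians of receptor minus control were compared with 100 shuffles of the gene order. Of 12230 positioned genes, 7956 lay in blocks.

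The fit was tested on simulated data of independent arrays, with 1 spread per gene taken from the fit for all groups. The real receptor arrays varied more than the control arrays and were paired by number, so these rates need not hold for the data. Of genes with a planted change of 2-fold, 92.8% were recovered for the unliganded receptor, 91.6% for estradiol in receptor cells, 89.6% for estradiol in control cells, 90.1% for the receptor under estradiol and 60.9% for the difference in response. For a change of 1.5-fold these were 43.9%, 33.4%, 37.6%, 42.4% and 7.76%. Between 3.24% and 5.44% of the calls were false.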

Results

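Expression was measured on 12 arrays of EA.hy926 endothelial cells in 4 groups of 3: control and receptor cells, each with vehicle or with 10 nM estradiol for 16 h. Between 18441 and 19747 probes per array were detected (39.0% to 41.7%), and the median raw intensity ran from 105 to 121. Receptor and control cells separated along the first principal component, which held 44.8% of the variance, and the receptor replicates separated from each other along the second, with 21.6%. Control replicates lay close together. The median SD of a gene between arrays of a group was 0.117 and 0.111 log2 in control cells under vehicle and estradiol, and 0.195 and 0.197 in receptor cells.

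**Figure D1:**
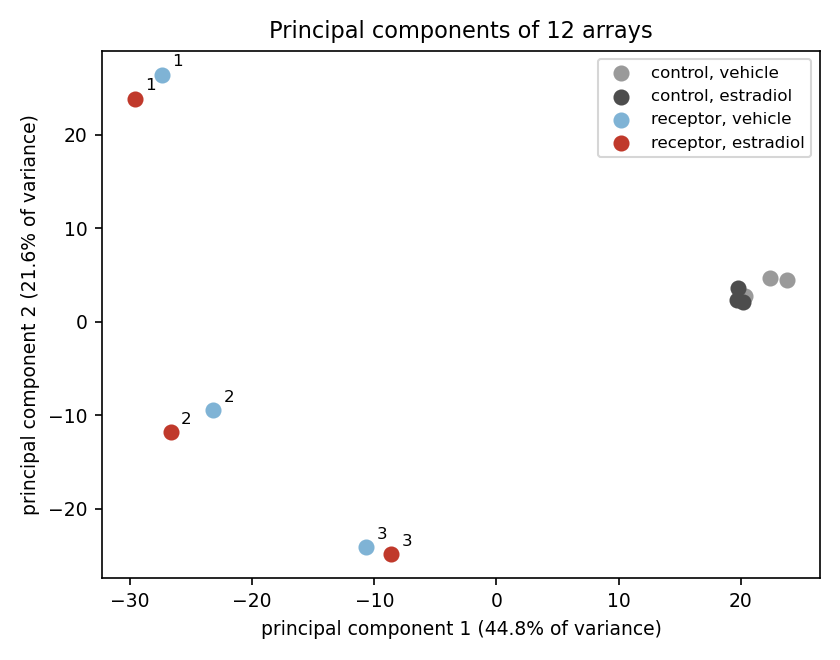
The first and second principal components of the 15249 genes, with 44.8% and 21.6% of the variance on the axes, 1 point per array and replicate numbers at the receptor arrays. The vehicle and estradiol arrays of a receptor replicate lie side by side, far from the other receptor replicates, while the 6 control arrays cluster.

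The probe for ESR1, the gene of the transfected receptor, was detected on 0 of 12 arrays. Its detection p ran from 0.103 to 0.681 and its raw intensity from 96.9 to 122. The mean normalized log2 level was 4.54 ± 0.10 (SD, n = 6) in control cells and 4.50 ± 0.12 (SD, n = 6) in receptor cells, a difference of -0.04 (exact two-sided permutation test over 924 splits, p = 0.481). The labels report receptor protein by western blot. The files do not say whether this probe matches the part of the transcript that the vector carried, so the arrays give no measure of the receptor's level.

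The comparison of vehicle-treated receptor and control cells asks what the receptor does without added hormone. It also holds any other difference between the transfected cell populations, which the design does not separate from the receptor. Several of the strongest decreases in receptor cells were in genes of secreted proteins, while other such genes, APLN and CCL2 among them, rose. Secreted proteins were not tested as a group. The chemokines CCL14 and CCL15 were 16.1-fold and 9.71-fold lower, the growth factor BMP4, which steers vessel and tissue patterning, was 10.4-fold lower, and the protease inhibitor CST1 was 19.9-fold lower. Receptor vehicle levels of CCL14 were 4.563, 5.214 and 4.755, near the 4.54 of the undetected ESR1, so the background limits its fold. Interferon-stimulated genes, targets of TGF-beta and BMP signalling, matrix genes and endothelial genes were lower as groups, and genes of mitosis and cholesterol synthesis higher. None of these 6 group shifts was called with an estimated correlation between genes (adjusted p = 0.288 for interferon-stimulated genes, 0.194 for TGF-beta and BMP targets, 0.358 for matrix, 0.425 for endothelial, 0.188 for mitosis and 0.194 for cholesterol synthesis genes with an estimated correlation). NOS3, the endothelial nitric oxide synthase, was 2.12-fold lower. In limma, 1302 of 15249 genes were called, 571 higher and 731 lower, of which 231 changed at least 2-fold.

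Among the strongest decreases, CST1 had a log2 fold of -4.32 ± 0.35 (SE, adjusted p = 1.61e-05), CCL14 of -4.01 ± 0.24 (1.75e-06) and CCL15 of -3.28 ± 0.21 (2.60e-06). The chemokine CCL23 had -3.82 ± 0.83 (adjusted p = 0.0150), with differences of -5.86, -2.93 and -2.66 in replicates 1, 2 and 3. CLIP3, a microtubule-associated protein, was at least 11.3-fold lower (adjusted p = 9.09e-10), since it was detected on 0 of 3 receptor arrays. BMP4 had -3.38 ± 0.23 (3.28e-06). The strongest increase was that of SYTL2, a vesicle-trafficking protein, with 3.45 ± 0.36 (1.32e-04). CALB2, the calcium-binding protein calretinin, was at least 4.70-fold higher (adjusted p = 0.00209). FAM107A, an actin-associated protein, had 2.44 ± 0.15 (2.56e-06), and SLC6A12, a betaine and GABA transporter, 2.16 ± 0.19 (3.68e-05). APLN, which encodes the vascular peptide apelin, had 2.02 ± 0.14 (4.16e-06), and the calpain-family gene CAPN11 had 2.02 ± 0.30 (0.00141). All of these had the same direction in 3 of 3 replicates, which the rule for naming them required.

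With camera at the preset correlation, interferon-stimulated genes had the smallest adjusted p of the lists. Fry gave epithelial markers a smaller one (adjusted p = 4.16e-05 against 0.0231). Of 29 interferon-stimulated genes measured, 12 were called lower and 0 higher (19 lower when adjusted over the list alone), with a median log2 fold of -0.65 and an adjusted p of 1.25e-10. HERC5, an ubiquitin-like ligase for ISG15, fell by 2.08 log2, IFITM1, which blocks virus entry, by 1.86, and USP18, which removes ISG15, by 1.07. The group's adjusted p = 0.288 with an estimated correlation. Of 17 TGF-beta and BMP targets, 8 were called lower and 0 higher (8 over the list alone), with a median of -0.35 (adjusted p = 5.38e-05, and adjusted p = 0.194 with an estimated correlation). ID3 and ID1, repressors of differentiation that respond to BMP, had log2 folds of -1.38 ± 0.14 and -1.22 ± 0.13. Of 35 matrix, integrin and protease genes, 10 were called lower and 0 higher (14 when adjusted over the list alone), with a median of -0.29 (adjusted p = 9.66e-05, and adjusted p = 0.358 with an estimated correlation). The integrin subunit ITGB3 had -0.93, the matrix protease MMP2 -0.88, and the basement membrane proteoglycan HSPG2 was at least 1.42-fold lower.

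Of 26 endothelial identity genes, 8 were called lower and 2 higher (11 and 2 when adjusted over the list alone). The median was -0.44 (adjusted p = 1.15e-04, and adjusted p = 0.425 with an estimated correlation). NOS3 had a log2 fold of -1.08 ± 0.16 (adjusted p = 0.00151), the anticoagulant surface protein THBD -1.06 ± 0.11 (1.25e-04) and the transcription factor SOX18 -0.77 ± 0.11 (0.00151). The general endothelial markers VWF, at -0.85 ± 0.61 (0.418), and PECAM1, at -0.37 ± 0.20 (0.269), were not called. Their replicates differed, with 0.69, -1.54 and -1.70 for VWF and 0.06, -0.47 and -0.70 for PECAM1 in replicates 1, 2 and 3. Without replicate 1 of both receptor groups both were called lower, VWF at -1.62 (adjusted p = 2.40e-04) and PECAM1 at -0.59 (0.0226). Of 9 epithelial markers, chosen because the line has a carcinoma parent, 4 were called higher and 1 lower, the same numbers over the list alone, with a median of 0.61 (adjusted p = 0.00641, and adjusted p = 0.188 with an estimated correlation). The keratins KRT18 and KRT80 had 0.87 ± 0.15 and 0.84 ± 0.13, while the mucin MUC1 had -1.15 ± 0.18.

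Of 29 mitosis genes, 9 were called higher and 0 lower (15 when adjusted over the list alone), with a median of 0.35 (adjusted p = 4.56e-10, and adjusted p = 0.188 with an estimated correlation). The spindle checkpoint kinases TTK and BUB1 had log2 folds of 0.93 and 0.72, and the DNA topoisomerase TOP2A 0.55. The proliferation marker MKI67, at 0.11 (adjusted p = 0.660), and the cyclin CCND1, at -0.22 (0.280), were not called. Of 34 DNA replication genes, 2 were called higher and 1 lower (6 and 1 over the list alone), with a median of 0.18 (adjusted p = 0.00217, and adjusted p = 0.194 with an estimated correlation). The helicase subunit MCM5 had 0.49, the nucleotide reductase subunit RRM1 0.34 and the replication factor GINS4 -0.48. Of 23 cholesterol synthesis genes, 6 were called higher and 0 lower (11 when adjusted over the list alone), with a median of 0.33 (adjusted p = 3.67e-05, and adjusted p = 0.194 with an estimated correlation). HMGCS1, an early enzyme of the pathway, had 0.55, ACAT2 0.50 and EBP 0.39. Of 22 ATF4 targets, which answer to amino acid shortage, 4 were called higher and 1 lower (5 and 1 over the list alone), with a median of 0.21 (adjusted p = 0.00255, and adjusted p = 0.188 with an estimated correlation). The stress factor ATF3 had 1.31, the serine synthesis enzyme PHGDH 0.82 and the mTOR inhibitor DDIT4 0.65.

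Of 26 adhesion, chemokine and NF-kB genes, 5 were called higher and 0 lower (8 higher and 2 lower over the list alone), with a median of 0.31 (adjusted p = 0.0184, and adjusted p = 0.188 with an estimated correlation). The monocyte chemokine CCL2 had 0.69, TNFAIP2 0.49, and the leukocyte adhesion molecule SELE was at least 1.13-fold higher. The adhesion molecules ICAM1 (adjusted p = 0.723) and VCAM1 (0.278) were not called, and both were near background, with ICAM1 detected on 1 of 3 arrays in each group and VCAM1 on 1 of 3 control and 0 of 3 receptor arrays. All 10 of these group shifts lost their call with an estimated correlation, while fry called 12 lists.

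The other 13 lists showed no shift called by camera, and fry called 2 of them, leukocyte markers higher (adjusted p = 0.0271) and immediate early genes lower (0.0271). Of 25 angiogenic and Notch genes, 3 were called higher and 2 lower (adjusted p = 0.574), with NOTCH4 at 0.90 and the ligand JAG1 at -0.89. Of 26 genes of vascular tone and coagulation, 3 were called higher and 2 lower (adjusted p = 0.616), with the plasminogen activator PLAU at 0.84. Of 21 NRF2 targets, 2 were called higher and 1 lower (adjusted p = 0.923), with the reductase AKR1B10 at -1.93, malic enzyme ME1 at 1.02 and TXNRD1 at 0.40. Of 25 hypoxia and glycolysis genes, 2 were called each way (adjusted p = 0.933), with BHLHE40 at 0.90, the glucose transporter SLC2A1 at 0.73 and the glycolysis regulator PFKFB3 at -0.80. Of 24 p53 targets, 1 was called higher and 2 lower (adjusted p = 0.986), with the death receptor FAS at 0.89, GDF15 at -0.58 and MDM2 at -0.47. Of 12 mesenchymal markers, 1 was called higher and 2 lower (adjusted p = 0.986), with the cadherin CDH2 at 0.63, the protease FAP at -0.75 and TAGLN at -0.58. Of 7 leukocyte markers, 2 were called higher (adjusted p = 0.342), ITGAX at 0.99 and LCP1, at least 1.44-fold higher. Of 17 immediate early genes, 2 were called lower (adjusted p = 0.409), JUNB at -0.63 and ZFP36 at -0.72. Of 15 nuclear receptors and cofactors, 2 were called lower (adjusted p = 0.986), with the retinoid receptor RXRA at -0.69.

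Of 18 measured estrogen-responsive genes, 1 was called higher and 1 lower (adjusted p = 0.398), the chaperone HSPB8 at 0.56 and the adenylyl cyclase ADCY9 at -0.65, and the classical targets PGR and GREB1 were not detected on enough arrays. Of 19 unfolded protein response genes 1 was called lower (adjusted p = 0.716), and of 20 antigen presentation genes 1 higher (adjusted p = 0.113). None of the 16 reference genes was called (adjusted p = 0.930). Signs of median, mean and test differed for the mesenchymal, vascular tone, NRF2, hypoxia and nuclear receptor lists, all without a shift called by camera.

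**Figure D2:**
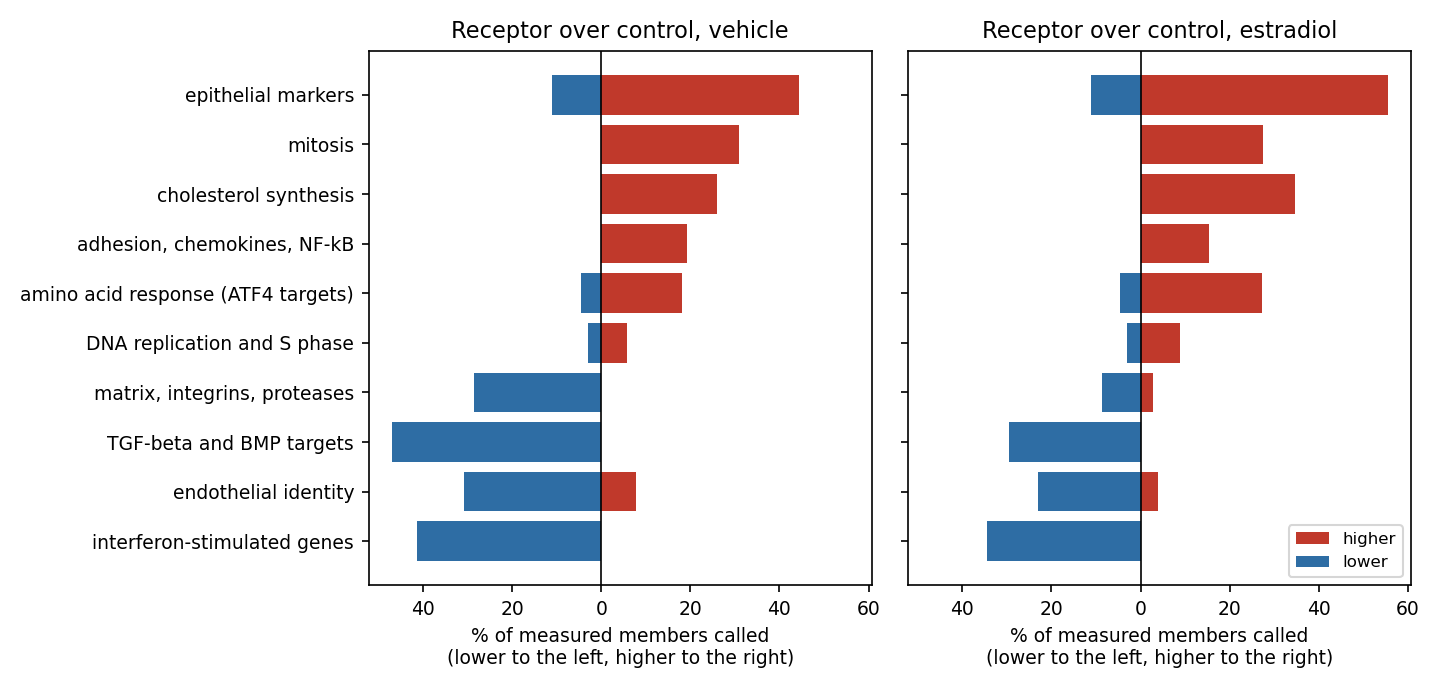
Percent of the measured members of 10 gene lists called higher (to the right) or lower (to the left) in receptor over control cells, under vehicle and under estradiol. Of the interferon-stimulated genes 12 of 29 were lower under vehicle and 10 of 29 under estradiol, and of the mitosis genes 9 and 8 of 29 were higher.

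The number of genes called for the unliganded receptor depended on single arrays. It was 589, 479 and 818 without control vehicle replicate 1, 2 or 3 and 647 without receptor vehicle replicate 2. Of the named genes, 68 of them called, 19, 21 and 10 lost their call without control vehicle replicate 1, 2 or 3, with adjusted p from 0.0503 to 0.148. Without receptor vehicle replicate 1, 2 or 3, 11, 13 and 5 did, with adjusted p from 0.0506 to 0.146. ACAT2, CCL2, CCL23, FAS, ITGB3, MCM5, SELE and ZFP36 lost it without either control vehicle replicate 1 or 2. ADCY9, EBP, GINS4, HMGCS1, MDM2, RASGRF1, RRM1, TNFAIP2 and TXNRD1 lost it without any of the 3 control vehicle arrays, HSPB8, JUNB and TAGLN without replicate 2, and FAP without replicate 1.

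Blocks of neighbouring genes moved together in receptor cells. Across blocks the shifts of replicates 2 and 3 correlated at 0.803, and those of replicate 1 with them at 0.345 and 0.149, so replicate 1 differed most. Of 156 blocks of 51 genes, 24 lay beyond all 100 shuffles of the gene order in at least 1 replicate. The limit from the shuffles was 0.302, 0.263 and 0.158 in replicates 1, 2 and 3, so a block past it in replicate 3 could shift as far in replicate 2 and not pass there, as did that from THNSL1 to HNRNPH3 at -0.20 in replicate 2 and -0.19 in replicate 3. The block from ZMYND11 to PRTFDC1 was lower in all 3, with medians of -0.40, -0.52 and -0.49 log2. The block from ARHGEF1 to BICRA had -0.54, -0.11 and -0.03, that from ZNF721 to DHX15 0.01, -0.45 and -0.42, and that from ZMYM6 to SVBP 0.31, -0.05 and 0.02. Control blocks, taken as each control replicate minus the other control replicates, stayed within 0.0622. That measure shows the spread between control replicates and cannot show a shift shared by a whole cell line. Over 20 other draws of the shuffles the number of blocks was 19 to 24, so 24 is the top of that range. Blocks shifted in any replicate held 166 of the 816 unliganded calls that lay in blocks (20.3%), and 15.4% of the genes. After the running median of neighbours was subtracted from each receptor array, 883 of 1180 calls among positioned genes kept their call and direction, and the 448 higher and 732 lower calls became 525 and 586. ITPKC, PFKFB3, GINS4, MDM2, JUNB, ADCY9 and TXNRD1 were among those that lost it, with PFKFB3 at -0.32 (adjusted p = 0.110) and ITPKC at -0.51 (0.0952).

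**Figure D3:**
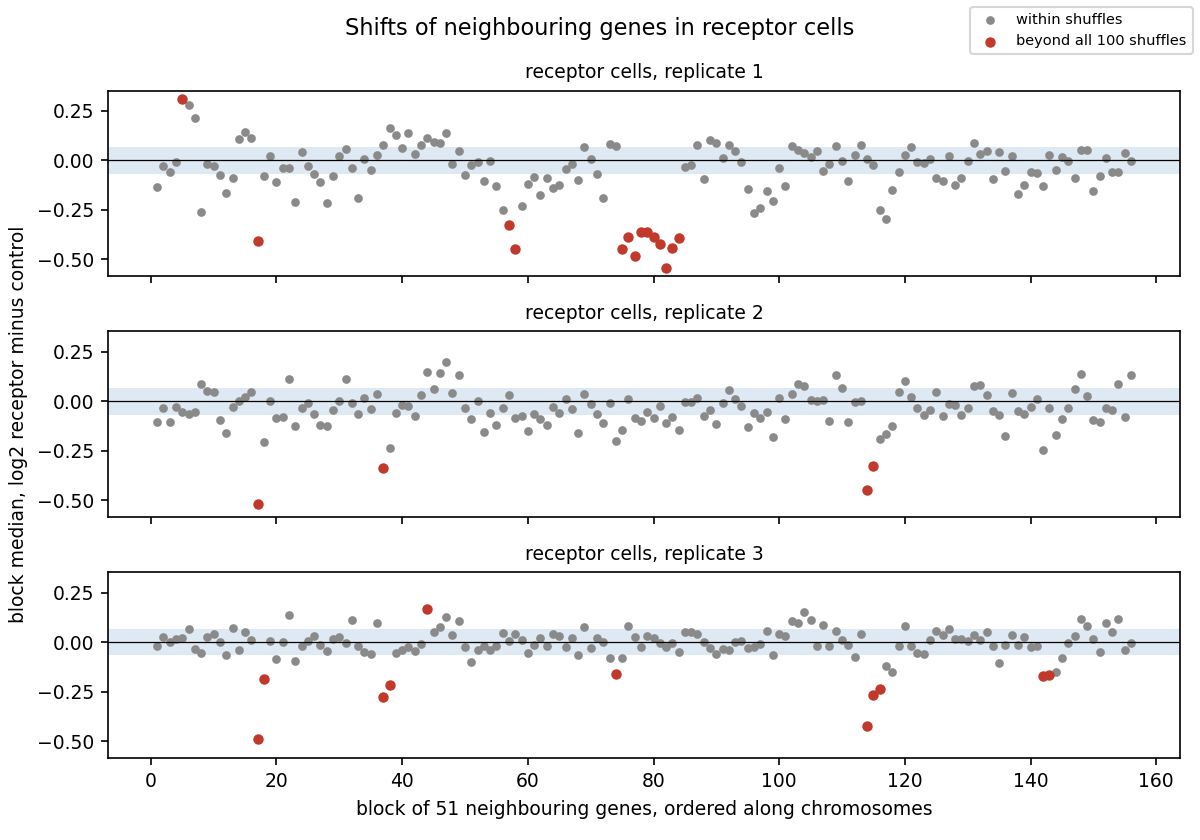
Median log2 difference of receptor over control for 156 blocks of 51 neighbouring genes in chromosome order, in receptor replicates 1, 2 and 3, with blocks beyond all 100 shuffles in red. The band is the range of each control replicate minus the other control replicates. Shifted blocks reach -0.54 in replicate 1, -0.52 in replicate 2 and -0.49 in replicate 3.

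Estradiol in receptor cells asks what the hormone adds. It raised a small set of genes and lowered none at the threshold. VASN, which encodes vasorin, a TGF-beta-binding surface protein, rose 5.31-fold, OLFML3, a secreted glycoprotein, 5.18-fold, and RASGRF1, an activator of Ras, 4.52-fold. INPP4B, a phosphoinositide phosphatase, and SMOX, a spermine oxidase, both rose 2.59-fold. In limma, 11 of 15249 genes were called, all higher in 3 of 3 replicates, which calls made on the same arrays favour. A total of 527 had an unadjusted p under 0.05, a smaller share than the 0.05 that tests without any change would give. This fit ignored the pairing of the receptor arrays by number, so differences between replicates widened its error. The low share therefore does not show that estradiol changed no further genes.

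The log2 folds were 2.41 ± 0.22 for VASN (SE, adjusted p = 3.13e-04), 2.37 ± 0.27 for OLFML3 (0.00218), 2.18 ± 0.14 for RASGRF1 (2.14e-05), 1.37 ± 0.13 for INPP4B (3.13e-04) and 1.37 ± 0.12 for SMOX (2.43e-04). CCN5, a matricellular protein listed as WISP2, had 1.36 ± 0.17 (0.00637), and B4GALT1, a galactosyltransferase, 1.34 ± 0.17 (0.00792). THBD had 1.03 ± 0.11 (0.00156) and CST4, a cystatin, 1.03 ± 0.16 (0.0321). TNIP1, which restrains NF-kB signalling, had 0.87 ± 0.14 (0.0456), and the inositol phosphate kinase ITPKC 0.82 ± 0.12 (0.0321). NOS3, at 0.05 ± 0.16, and the fixed examples VWF, PECAM1, KRT18, MKI67, CCND1, ICAM1, VCAM1 and SELE were not called, with MKI67 at 0.12 (adjusted p = 1.00) and SELE, detected on 0 of 3 receptor estradiol arrays, at least 1.13-fold lower (0.998).

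Of the 11 genes, 5 were also called for the unliganded receptor. THBD, CST4 and ITPKC, lower without hormone at -1.06, -2.41 and -0.74, went the opposite way with estradiol, and RASGRF1, at least 1.32-fold higher, and TNIP1, at 0.71, went the same way. Both comparisons use the receptor vehicle arrays with opposite sign, which favours opposite calls. Under estradiol THBD stood at a level of 8.16 ± 0.04 (SD, n = 3) in receptor cells and 8.06 ± 0.14 in control cells. CST4 stood at 6.12 ± 0.33 against 7.35 ± 0.05.

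**Figure D4:**
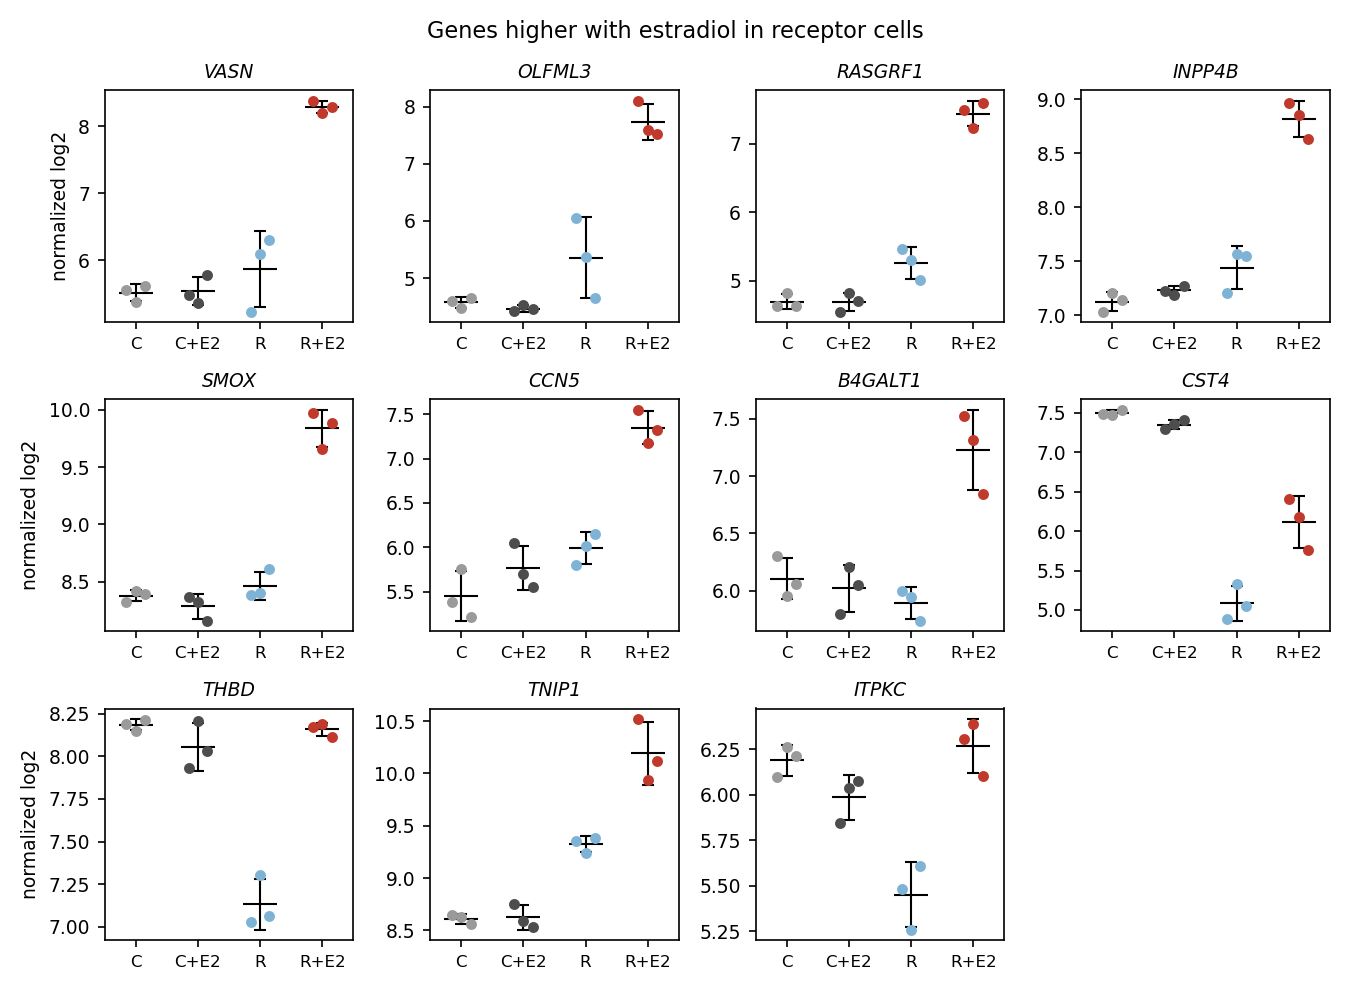
Normalized log2 level of the 11 genes called for estradiol in receptor cells, on 12 arrays: control cells with vehicle (C) or estradiol (C+E2) and receptor cells with vehicle (R) or estradiol (R+E2), 1 point per array, lines at the mean and bars of 1 SD. In each panel the 3 receptor arrays with estradiol lie above the 3 with vehicle, as for THBD with means of 8.16 and 7.13.

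As a group, genes of the unfolded protein response, which help proteins fold in the endoplasmic reticulum, rose with estradiol: 16 of 19 were higher, with a median log2 fold of 0.10 (adjusted p = 4.74e-04, and adjusted p = 0.0390 with an estimated correlation), although 0 were called singly. Shifts of other lists did not keep their call with an estimated correlation. ATF4 targets rose with a median of 0.10 (adjusted p = 0.00140, and adjusted p = 0.118 with an estimated correlation). NRF2 targets, with a median of 0.11 (adjusted p = 0.00240, and adjusted p = 0.161 with an estimated correlation), lost the call without receptor vehicle replicate 1 (adjusted p = 0.129). Of 18 estrogen-responsive genes 12 were higher, 0 called over all genes and 1 adjusted over the list alone, with a median of 0.07 (adjusted p = 0.00240, and adjusted p = 0.112 with an estimated correlation). Without receptor estradiol replicate 1 their adjusted p was 0.142. Cholesterol synthesis genes had a median of 0.11 (adjusted p = 0.00240, and adjusted p = 0.384 with an estimated correlation), and lost the call without receptor vehicle replicate 1 (adjusted p = 0.222) or receptor estradiol replicate 1 (0.480). Matrix genes had 0.06 (adjusted p = 0.00951, and adjusted p = 0.532 with an estimated correlation), and lost it without receptor vehicle replicate 3 (0.948) or receptor estradiol replicate 1 (0.824). TGF-beta and BMP targets had 0.11 (adjusted p = 0.0102, and adjusted p = 0.440 with an estimated correlation), and lost it without receptor vehicle replicate 1 (0.518) or receptor estradiol replicate 3 (0.428). Epithelial markers had a median of 0.02, with 2 of 9 called over the list alone (adjusted p = 0.0213, and adjusted p = 0.146 with an estimated correlation), and lost the call without receptor vehicle replicate 1 (0.222) or 3 (0.0825) or receptor estradiol replicate 2 (0.146) or 3 (0.0682). Interferon-stimulated genes had -0.15 (adjusted p = 0.0102, and adjusted p = 0.653 with an estimated correlation). Without receptor vehicle replicate 1 their median was 0.12 (adjusted p = 0.145), and without receptor estradiol replicate 2 or 3 the adjusted p was 0.665 and 0.847. Omitting 1 receptor array leaves the paired replicates unbalanced in this unpaired fit. Differences between replicates then enter the estradiol effect, here and in later omissions of a receptor array.

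Replicate numbers paired the receptor arrays, and the count depended on the model and the scaling. It was 1 when only the vehicle and estradiol arrays of receptor cells were fitted without pairing, and 3 with median scaling. With the replicate number as a block within each cell line, 35 genes were called. A fit of the 6 receptor arrays alone, paired by number, called 14, of which 8 were among the 11. CST4 lost its call without receptor vehicle replicate 1 (adjusted p = 0.109) or 3 (0.121) or receptor estradiol replicate 1 (0.113) or 2 (0.130). ITPKC lost it without receptor vehicle replicate 1 (0.0807) or 2 (0.203) or receptor estradiol replicate 1 (0.139) or 2 (0.130), and on subtraction of neighbouring genes (0.504). TNIP1 lost it without any of the receptor vehicle arrays (0.109, 0.225 and 0.121) or receptor estradiol replicate 1 (0.0955) or 3 (0.0904), and B4GALT1 without receptor estradiol replicate 2 (0.0575).

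Estradiol in control cells shows what the hormone does without the transfected receptor. Most of the genes that rose in receptor cells showed little change here: VASN had a log2 fold of 0.02 ± 0.22 (SE, n = 3 per group), SMOX of -0.09 ± 0.12, THBD of -0.13 ± 0.11 and INPP4B of 0.10 ± 0.13. CCN5 had 0.32 ± 0.17, not called. RASGRF1 and OLFML3 were detected on 0 of the 6 control arrays. In limma, 0 of 15249 genes were called, with a smallest adjusted p of 1.00, and 351 genes had an unadjusted p under 0.05, again a share below 0.05. The fit took its spread from all groups, and receptor arrays varied more than control arrays, so the low share does not show an absence of change. No other tool was run on single genes, and 0 were called in every alternative setting, with a smallest adjusted p of 0.123 with array weights. Of the fixed examples, MKI67 had -0.47, VWF -0.44 and NOS3 -0.16, none of them called. Matrix genes were lower in 26 of 35 cases, with a median of -0.11 (adjusted p = 0.00703, and adjusted p = 0.906 with an estimated correlation), and fry gave an adjusted p of 0.975. That shift lost its call without control vehicle replicate 1 (adjusted p = 0.227) or 2 (0.348) or control estradiol replicate 1 (0.0808).

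The difference between the responses tests whether estradiol acted differently in receptor and control cells. A difference was called for 5 of the 11 estradiol genes, all of which responded more in receptor cells: RASGRF1, VASN, SMOX, INPP4B and THBD. The extra log2 response was 2.18 ± 0.20 for RASGRF1 (SE, adjusted p = 0.00125), 2.39 ± 0.31 for VASN (0.0214), 1.47 ± 0.16 for SMOX (0.00593), 1.27 ± 0.18 for INPP4B (0.0260) and 1.16 ± 0.16 for THBD (0.0227). OLFML3, at 2.48 ± 0.38 (0.0516), B4GALT1, at 1.42 (0.135), CST4, at 1.18 (0.266), ITPKC, at 1.02 (0.135), CCN5, at 1.04 (0.769), and TNIP1, at 0.85 (0.769), were not called. In limma 437 genes had an unadjusted p under 0.05, again a share below 0.05. This fit too ignored the pairing, so the share does not show an absence of further differences.

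Unfolded protein response genes responded more in receptor cells, with 17 of 19 higher and a median of 0.14 (adjusted p = 6.60e-04, and adjusted p = 0.0547 with an estimated correlation), as did estrogen-responsive genes, with 14 of 18 higher, 1 of them called over the list alone, and a median of 0.13 (adjusted p = 6.69e-04, and adjusted p = 0.0609 with an estimated correlation). Matrix genes had 0.15 (adjusted p = 7.52e-05, and adjusted p = 0.384 with an estimated correlation), without a call when receptor vehicle replicate 3 (adjusted p = 0.0732) or receptor estradiol replicate 1 (0.0665) was left out. TGF-beta and BMP targets had 0.11 (adjusted p = 0.04996, and adjusted p = 0.493 with an estimated correlation), and DNA replication genes -0.09 (adjusted p = 0.04996, and adjusted p = 0.384 with an estimated correlation). Both lost the call in 6 of the 12 omissions of an array.

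The count of 5 became 9 with the replicate number as a block within each cell line. It was 2 without control vehicle replicate 1, 2 or 3, control estradiol replicate 1 or receptor estradiol replicate 1 or 2, and 3 without control estradiol replicate 2 or 3. RASGRF1 and SMOX kept their call in each of the 12 omissions. VASN lost it in 7 (adjusted p from 0.0679 to 0.119), INPP4B in 8 (0.0772 to 0.143) and THBD in 9 (0.0511 to 0.120). OLFML3 was called without receptor vehicle replicate 1 (0.00168) or 3 (0.0210), and B4GALT1 (0.0217) and CST4 (0.0291) without receptor estradiol replicate 3.

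The comparison of receptor and control cells under estradiol shows which differences between those cells were called with hormone. The same chemokines, BMP4 and CLIP3 were low, SYTL2 and APLN were high, and the estradiol-induced genes OLFML3, RASGRF1 and VASN joined the strongest increases. OLFML3 was at least 7.28-fold higher and RASGRF1 at least 5.92-fold, VASN 6.71-fold and SYTL2 8.78-fold, along with HAVCR2, an immune checkpoint receptor (6.06-fold), and PDE7B, a cAMP phosphodiesterase (5.29-fold). CCL23 was 20.5-fold lower (receptor levels of 5.58, 8.68 and 8.80 in replicates 1, 2 and 3, so replicate 1 widens the fold), CCL14 16.3-fold, CLIP3 at least 11.1-fold, the GTPase gene GIMAP7 10.1-fold, BMP4 9.93-fold and CCL15 9.80-fold. The background limits the CCL14 fold here too, with receptor estradiol levels of 4.441, 5.2 and 5.138. In limma 1159 genes were called, 494 higher and 665 lower, and 221 changed at least 2-fold. Subtracting the shift of neighbouring genes turned 444 higher and 678 lower calls among positioned genes into 535 and 512. That step centres each receptor array on its neighbouring genes and can by itself even the calls. It therefore does not decide whether the excess of lower calls is real.

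NOS3 was lower, at -0.87 ± 0.16 (SE, adjusted p = 0.00594), and so was CST4, at -1.24 ± 0.16 (4.45e-04). THBD, at 0.10 ± 0.11 (0.642), and ITPKC, at 0.28 ± 0.12 (0.197), were not called. Interferon-stimulated genes were lower for 10 of 29 (23 when adjusted over the list alone, adjusted p = 6.35e-13, and adjusted p = 0.244 with an estimated correlation), with HERC5 at -2.14. Mitosis genes were higher for 8 of 29 (17 over the list alone, adjusted p = 3.33e-12, and adjusted p = 0.0999 with an estimated correlation), with MKI67 at 0.70 (adjusted p = 0.00871). Control levels of MKI67 were 4.646, 4.925 and 4.556 with estradiol, close to the 4.54 of the undetected ESR1, and 5.077, 5.231 and 5.225 with vehicle. Receptor levels were 5.183, 5.614 and 5.419 with estradiol and 5.152, 5.410 and 5.304 with vehicle, so lower control levels made most of this difference. Cholesterol synthesis genes were higher for 8 of 23 (13 over the list alone, adjusted p = 2.76e-08, and adjusted p = 0.0999 with an estimated correlation), with ACAT2 at 0.59. Of the ATF4 targets 6 of 22 were higher and 1 lower (9 and 1 over the list alone, adjusted p = 1.10e-05), with DDIT4 at 0.99. Of the adhesion, chemokine and NF-kB genes 4 of 26 were higher (8 higher and 1 lower over the list alone, adjusted p = 3.57e-04), with TNFAIP2 at 1.17, and of the epithelial markers 5 of 9 were higher and 1 lower (the same over the list alone, adjusted p = 4.71e-04), with KRT80 at 0.82. These last 3 lists kept their call, with adjusted p = 0.0401 with an estimated correlation for each.

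TGF-beta and BMP targets were lower for 5 of 17 (5 over the list alone, adjusted p = 0.00413, and adjusted p = 0.378 with an estimated correlation), with ID1 at -1.26. Endothelial genes were lower for 6 of 26 and higher for 1 (7 and 2 over the list alone, adjusted p = 0.00658, and adjusted p = 0.522 with an estimated correlation), with SOX18 at -0.98 and CD34 at 1.02. That shift lost its call without receptor estradiol replicate 2 (adjusted p = 0.0544) or 3 (0.0720). Genes of vascular tone were higher for 3 of 26 and lower for 2 (6 and 2 over the list alone, adjusted p = 0.0375, and adjusted p = 0.378 with an estimated correlation), with the arginase ARG2 at 0.77 and the cyclooxygenase PTGS1 at -1.66, and lost the call without control estradiol replicate 1 (0.0657) or receptor estradiol replicate 1 (0.348). PTGS1 itself lost its call without control estradiol replicate 1 (0.0775), 2 (0.0551) or 3 (0.0559) or receptor estradiol replicate 2 (0.0824). Of the lists called under vehicle, matrix genes, with 3 of 35 lower and 1 higher (adjusted p = 0.247), and DNA replication genes, with 3 of 34 higher and 1 lower (0.148), were not called under estradiol. The gene count was 578, 582 and 603 without control estradiol replicate 1, 2 or 3, 643 without receptor estradiol replicate 2, and 748 when the groups compared were fitted alone.

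Under vehicle and under estradiol, 749 genes were called for the receptor in the same direction and 0 in opposite directions, with 553 called under vehicle alone and 410 under estradiol alone. Across genes the log2 folds of these comparisons correlated at 0.83. The comparisons share no arrays, but same-numbered receptor arrays of both treatments deviated together, so the states of the replicates enter both. The agreement is therefore no independent repeat of the receptor effect. Genes are not independent replicates.

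The study's question of whether estradiol counters the unliganded receptor was put to all genes. Across genes, which are not independent, the unliganded and estradiol effects in receptor cells correlated at -0.149. They share the receptor vehicle arrays with opposite sign, and simulations of independent arrays without any effect gave -0.499 (-0.523 to -0.475). The receptor arrays are paired by number, which makes the value without effects less negative, so this range is no baseline for the observed value. Without receptor estradiol replicate 3 it was 0.077. Of the 1302 unliganded genes 60.4% moved the opposite way with estradiol, and simulations without an estradiol effect, again of independent arrays, gave 62.7% to 66.8%. The mean receptor effect over both treatments, which is free of that sharing, correlated with the estradiol effect at 0.073. Simulations gave -0.032 to 0.027, but swapping vehicle and estradiol labels within pairs gave up to 0.157, and the sign turned without receptor vehicle replicate 1 (-0.0039) or 3 (-0.151). Each such omission also breaks a pair, so differences between replicates enter the estradiol effect. Whether estradiol reversed the unliganded effect in general stays open, and genes called in opposite directions were THBD, CST4 and ITPKC. For estradiol in receptor cells, THBD kept its call in 22 of 24 alternative settings, CST4 in 9 and ITPKC in 10. ITPKC lost both calls on subtraction of neighbouring genes. Estradiol effects in receptor and control cells correlated across genes at 0.00167.

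**Figure D5:**
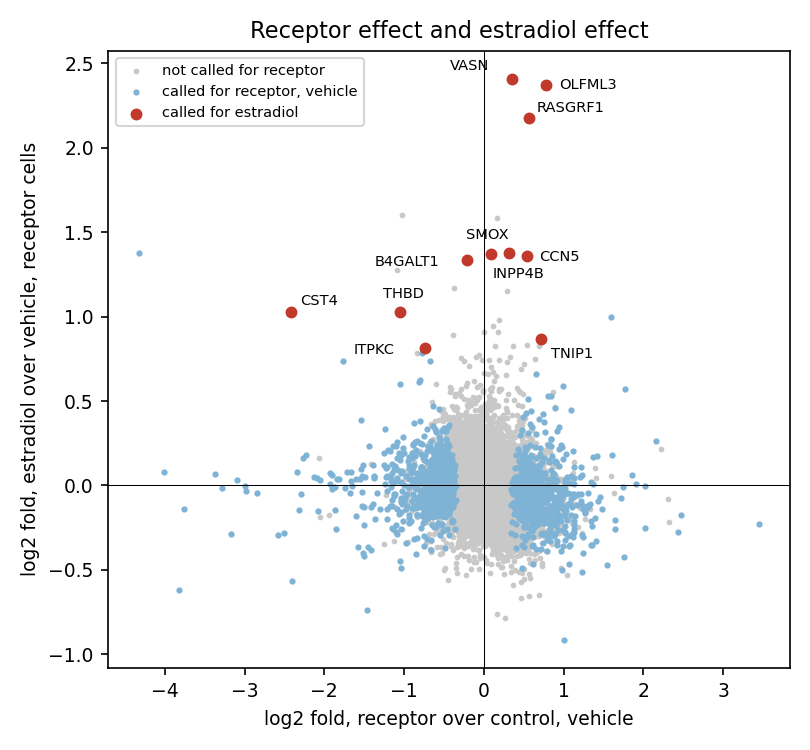
Log2 fold of receptor over control under vehicle (horizontal) against log2 fold of estradiol over vehicle in receptor cells (vertical), 1 point per gene, with genes called for the unliganded receptor in blue and the 11 called for estradiol in red. CST4 (-2.41, 1.03), THBD (-1.06, 1.03) and ITPKC (-0.74, 0.82) lie in the upper left, and VASN, OLFML3 and RASGRF1 at the top.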

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

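The tests of a separate merging of arrays, of a state shared by same-numbered arrays, of the shuffled gene order, of gene-dense regions, of a receptor effect common to all replicates and of splits that part every pair in both lines were chosen after the results were seen, and the other tests of this part were set beforehand.

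Some estradiol responses differed between receptor and control cells by an interaction test. In log2, the response in receptor cells exceeded that in control cells by 2.39 for VASN, 2.18 for RASGRF1, 1.16 for THBD, 1.47 for SMOX and 1.27 for INPP4B. List medians differed by 0.126 for estrogen-responsive genes, -0.0937 for DNA replication, 0.149 for matrix genes, 0.136 for the unfolded protein response and 0.108 for TGF-beta and BMP targets. None of these 5 list shifts was called with an estimated correlation (adjusted p = 0.0609, 0.384, 0.384, 0.0547 and 0.493), and those of DNA replication and of TGF-beta and BMP targets lost their call in 6 of the 12 omissions of an array. Because the numbers pair the receptor arrays, the count was compared with the 32 splits that part every pair in both lines. Of these 5 gave at least the real 5 genes, the highest other giving 7, but all 5 kept the real grouping of the receptor arrays and so carried their response to estradiol. The 24 splits that mixed vehicle and estradiol arrays of the receptor cells gave 0. Of 100 splits drawn without regard to pairs, 4 gave at least 5. The receptor arrays part their pairs in 4 ways, too few for a share under 0.05. For the comparisons of 3 arrays with 3, the 10 possible splits are too few for a share under 0.05. The real split was the largest for the unliganded receptor (1 of 10 splits, 1302 genes, highest other 0) and for the receptor under estradiol (1 of 10, 1159, highest other 0). Estradiol in control cells gave 0 in all 10 of 10. For estradiol in receptor cells 3 of 10 splits gave at least the real 11, and the highest other, receptor vehicle replicates 1 and 2 with receptor estradiol replicate 1 against the rest, gave 488, which points to a structure of the samples by replicate. Of the 4 splits that part all pairs, the real one gave 11 and the others 0.

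Receptor replicates differed from each other more than control replicates. Setting replicate 1 apart from the other receptor arrays called 1134 genes, setting replicate 3 apart called 177 and replicate 2 0, against 0 for each control replicate. Whether replicates 1 and 2 were merged separately is not known beyond 1 probe missing on their 4 arrays. Such a merging would set replicate 3 apart, which gave 177 genes and not the highest count, against it as the whole cause. The ratio of the median gene SD, receptor over control, stayed at 1.65 or more in 5 normalizations, against the normalization as the whole cause. Same-numbered vehicle and estradiol arrays deviated together, with a lowest correlation of 0.390 across genes, consistent with a state that a replicate number shares, which may be a clone, a passage or a harvest day, none of which the labels give.

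Blocks of neighbouring genes were shifted in receptor replicates. The largest block shift exceeded the largest of 100 shuffles by at least 1.79 times in each replicate (1.76 to 2.10 over 20 other draws), and block shifts of vehicle and estradiol arrays correlated at 0.768 or more, against a chance arrangement and against array noise. Of the shifted blocks, 4.17% were shifted in all 3 replicates, under limits that differed between replicates, against an effect of the receptor common to all. Copy number differences between replicates may contribute, since in shifted blocks a median of 84.3% of the genes lay on the side of the shift in estradiol arrays when the block was chosen in vehicle arrays (72.5% to 94.1% over 26 block and replicate pairs), but regional regulation would give the same. A response of gene-dense regions to hybridization cannot be told apart for replicate 1, where 59.0% of the densest blocks lay under -0.1, between the bounds set for the test.

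Whether shifted blocks account for the unliganded calls stays partly open. Blocks past the shuffle limit in any replicate held 166 of the 816 unliganded calls that lay in blocks (20.3%). That argues against these blocks as the source of most of those calls, but does not cover shifts under the limit. The running median of neighbours was subtracted from each receptor array, in shifted blocks or not. After that, 74.8% of the calls among positioned genes kept their call and direction. This lay under the 80% set as the bound against shifted blocks as the cause and over the 50% set for it. CST1, CCL14, CLIP3, BMP4 and CCL15 kept their calls after the subtraction. Their folds far exceeded the largest block shift, 0.54 log2, so the subtraction could hardly remove their calls and does not test them. Effects of the receptor itself and other differences between the transfected cell populations are not separated by this design, because the labels do not say how many independent populations the arrays hold.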

How the results depend on the processing

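The within-line and random replicate blocks, the omission of a replicate from both receptor groups, the paired fit, the subtraction of neighbouring genes and the other draws of the shuffles were chosen after the data were seen. Named genes called in the main setting kept their direction in the alternatives run, while some uncalled ones crossed 0, such as ICAM1 (unliganded receptor, -0.348 to 0.101) and VWF (estradiol in receptor cells, -0.735 to 0.761). The lower calls outnumbered the higher ones for the receptor under estradiol in the main setting, but not after the subtraction of neighbouring genes (535 higher and 512 lower), which can by itself even the calls. The count of 0 for estradiol in control cells stood in every setting (unadjusted p under 0.05 for 351 genes in the main setting), and ESR1 stayed without a difference (-0.0171 to -0.0845 on leaving out an array). For each change named here the cause was not tested, except where fewer arrays or a fold minimum account for it by construction. With median scaling the counts were 445 (unliganded), 3 (estradiol in receptor cells), 0 (difference in response) and 464 (receptor under estradiol). Fitting only the groups compared gave 1 for estradiol in receptor cells and 748 under estradiol. A trended robust variance gave 17 for estradiol in receptor cells. Array weights gave 3020, 9 (difference) and 2248, and a minimum of 1.5-fold 798 and 731 for the receptor comparisons. A replicate block within each line gave 35 for estradiol in receptor cells and 9 for the difference, and a random block 46 and 11. Omitting replicate 1, 2 or 3 from both receptor groups gave 1979, 637 and 2375 for the unliganded receptor and 1803, 602 and 2287 under estradiol, and without replicate 2 there were 5 for estradiol in receptor cells and 2 for the difference. Camera with an estimated correlation called 0 list shifts for the unliganded receptor instead of 10, and other settings 9 to 12.

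Leaving out each array gave 479 to 1555 genes for the unliganded receptor, 578 to 1687 under estradiol, 9 to 14 for estradiol in receptor cells and 2 to 7 for the difference. The correlation of unliganded and estradiol effects ran from -0.379 to 0.0770, and that of the mean receptor effect from -0.151 to 0.325, with -0.00394 without receptor vehicle replicate 1. The median of interferon-stimulated genes ran from -0.357 to 0.115 for estradiol in receptor cells and from -0.309 to 0.199 for the difference, with both upper values without receptor vehicle replicate 1 and both lower ones without receptor estradiol replicate 1. In these ranges, omitting 1 receptor array also breaks a pair and lets differences between replicates into the estradiol effect. Of 1437 checks of genes named for the unliganded receptor, outside omissions of an array, 1323 kept their side of the threshold, 103 fell below it and 9 rose above it. Of 357 for estradiol in receptor cells, 297 kept it and 47 fell below. A slide block was not run because the files name no slides. Genes near the background, such as ESR1, RASGRF1 and OLFML3 in control cells, have folds that the background limits.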

Other observations

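The genes named in this part were taken from a fit chosen after the data were seen, and the test of partial receptor activity was set before its result, with the holding out of each replicate added afterwards. With the replicate number as a block within each cell line, estradiol in receptor cells called 35 genes, among them the 11 reported and 24 further ones. All 24 were higher in 3 of 3 replicates, which selection on the same differences favours. The fit of the receptor arrays alone, paired by number, called fewer genes, and which of the 24 it called is not reported here. DHRS3, a retinal reductase, had a log2 fold of 1.61 ± 0.14 (SE, adjusted p = 0.00317), and PTGS2, the inducible cyclooxygenase of prostaglandin synthesis, 1.28 ± 0.12 (0.00396). SLCO2A1, a prostaglandin transporter, had 1.17 ± 0.18 (0.0480). The keratins KRT19 and KRT15 had 1.58 ± 0.17 (0.0102) and 0.94 ± 0.09 (0.00370). SELP, the adhesion molecule P-selectin, had 0.73 ± 0.08 (0.0121), the growth factor binding protein IGFBP3 0.89 ± 0.11 (0.0178), and SPRY1, an inhibitor of growth factor signalling, 0.74 ± 0.10 (0.0288). In the fit without a block none of these 8 was called, with adjusted p from 0.0934 to 1.00. In that fit their responses were not called as different between receptor and control cells, with adjusted p from 0.917 to 1.00.

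A partial activity of the receptor without added hormone could raise estradiol-induced genes already under vehicle. This hypothesis was tested on 61 genes chosen in receptor replicates 1 and 2 for a rise with estradiol at an unadjusted p under 0.001. In vehicle-treated replicate 3, 32 of the 61 were higher than in control cells (exact binomial p = 0.798), against 49.1% of all genes. That p counts co-regulated genes of 1 array as independent. Chosen in the same way with replicate 1 or 2 held out, 34 of 52 genes (65.4%) and 17 of 37 (45.9%) were higher, against 47.2% and 47.1% of all genes. The replicates differed, so the hypothesis stays open. With estradiol, 57 of the 61 genes rose in replicate 3 (exact binomial p = 4.85e-13). That p too counts co-regulated genes of 1 replicate as independent. With replicate 1 or 2 held out, 46 of 52 and 37 of 37 rose in the replicate held out.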
